A study of Mus musculus with 3 samples.

How the data were processed

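Tail genomic DNA of 3 male mice was amplified by PCR with primers specific for the tyrosinase gene, and Illumina libraries were made from the products, per the labels' protocols. The deposited file of each mouse is an allele table around the guide: each line holds an aligned allele, the reference it was aligned to, whether it was marked as unedited, the number of deleted, inserted and substituted bases, and its reads. Reads are given as a count per allele, not normalized, and as a percent of the reads of the library, both as deposited by the authors. The deposited percent of each allele equals its count over the total of its table, and the percents sum to 100 in each library, as checked on the files. The submitters' processing notes name cutadapt, without a version, and the genome build mm10. The aligner and the allele caller, and any filters on read quality, were not given in the sources used here. No molecular identifiers are described, so PCR duplicates and PCR errors are counted as reads.

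The deposited numbers of deleted and inserted bases were above 0 only for gaps that touch the expected cut, and those of substituted bases only for changes at the 2 bases beside it, as checked on the files. An indel read was therefore a read of an allele with a deposited deleted or inserted base number above 0. Gaps and substitutions elsewhere were read from the deposited pairwise alignments. The deposited base numbers include bases beyond the window, so lengths of gaps that cross its edge were taken from them. The direction of deletions from the cut was instead counted from bases inside the window only. Indel alleles were merged by their gaps, ignoring substitutions, with inserted bases kept apart up to 3 bases, which gave 66 indel alleles from the 223 deposited lines of indel alleles over the 3 tables. Because both bases before the cut are A, an inserted A is placed at the cut by the deposited alignment among equivalent placements.

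Shares were computed per mouse with exact Clopper-Pearson intervals at 95%, and a share of 0 was given the limit of 3 counts over the total. This limit lies below the exact two-sided upper bound, which was given instead for A19C in inserted-A reads. With 118665 to 172680 reads, 1 read is worth 0.000843%, 0.000579% and 0.000836% of reads in mice 1, 2 and 3. Means and SDs were taken over the mice, with n = 3. Within-mouse comparisons used exact two-sided sign-flip permutation tests over the 3 mice, adjusted by Benjamini-Hochberg over 6 tests; their smallest p is 0.25. The samples are separate mice per the labels, which do not say whether they share a litter. Pairs of mice were compared by chi-square tests of read counts, by Fisher's exact test, and by permutation of allele labels (99999 permutations). Deletion homology was the number of identical bases at the ends of a single deletion inside the window, and its expectation came from all placements of the same length that touch the cut. The effective number of alleles was averaged over 1000 draws of 76 indel reads, and allele sharing over 100 draws of equal total reads.

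The alleles named in the text were fixed by a rule set before the data were examined: the 10 indel alleles with the highest mean share among those with at least 10 reads in every mouse, the 3 leading indel alleles of each mouse, the leading allele of each of 6 size classes, and the reference allele. Only 1 allele had at least 10 reads in every mouse, and by the deposited base numbers the class of insertion with deletion was empty. The rule therefore named 8 indel alleles. Alternatives covered the definition of an indel, minimum shares and reads per allele, leaving out each mouse, pooling reads, weighting by distinct alleles, alleles at the window edge, homology length and thinning. A match to the sequencing adapter was called where 20 bases of an allele fitted it with at most 4 differences. Gap reading, homology, intervals, thinning and the permutation test were tested on simulated data: 900 of 900 simulated gaps were recovered, and intervals covered the simulated indel share in 870 of 900 draws. Spectra of mice 1 and 3 drawn from a common source were called different in 2 of 100 simulations, and those drawn from their own sources in 100 of 100. Simulated reads were drawn independently, unlike PCR copies, so these rates hold for counting error only. The own sources were the observed spectra, which already differed, so the 100 of 100 is no separate evidence of a difference.

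Gene coordinates were taken from the RefSeq annotation of GRCm38.p6, matched by the symbol Tyr; no genome sequence was used here. Calculations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1, edlib 1.3.9.post1 and matplotlib 3.10.9.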

Results

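Amplicon sequencing was used to read the Tyr target site in tail genomic DNA from 3 male mice. Tyr encodes tyrosinase, the enzyme that catalyses the rate-limiting step of melanin synthesis. Per the labels, the mice came from crosses that combined a Cas9 gene kept silent by a floxed stop cassette with a tamoxifen-activated Cre recombinase under the broadly active CAG promoter, and a transgene cassette supplied the guide RNA. Tamoxifen, the drug that releases this Cre into the nucleus, was labelled at 75 mg/kg and given through breast milk. The dose that reached the sampled mice was not measured here. All 3 animals formed 1 group, and no untreated or guide-free sample was analysed here, so the internal background was taken from gaps away from the cut. The question named by the series design was which insertions and deletions the guide had left at the target. Depth was 118665 reads in mouse 1, 172680 reads in mouse 2 and 119605 reads in mouse 3.

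The Tyr gene (gene ID 22173) lies on chromosome 7 from 87424771 to 87493512 of GRCm38, the assembly also called mm10, a span of 68742 bases. Alleles were given over a window of 40 bases, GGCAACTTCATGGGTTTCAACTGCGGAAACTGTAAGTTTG, in which positions are counted from 1 at the 5′ end. The guide, AACTTCATGGGTTTCAACTG, covers positions 4 to 23, and its PAM, CGG, covers positions 24 to 26. Cas9 cuts 3 bases from the PAM, which places the expected cut between positions 20 and 21, that is between guide bases 17 and 18. The coordinates of the window within the gene and its exon were not given in the sources used here.

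Indels at the cut were a small minority of reads in all 3 mice, and their share varied widely between animals. Mouse 1 carried an indel in 913 reads, or 0.769% (95% Clopper-Pearson interval 0.720% to 0.821%). Mouse 3 carried 188 such reads, or 0.157% (0.136% to 0.181%), and mouse 2 carried 76, or 0.0440% (0.0347% to 0.0551%). The mean was 0.324% ± 0.390 (SD, n = 3), a spread larger than the mean itself, and leaving out mouse 1 brought it to 0.101%. Among alleles with at least 0.2% of reads, which left only the inserted A of mouse 1, it was 0.0781%. Reads without any gap made up 99.6% ± 0.401 of each library (SD, n = 3), and the reference sequence over the whole window made up 87.2% ± 0.430. The mouse with the deepest library, mouse 2, had the lowest indel share.

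Mouse 1 exceeded mouse 2 by a factor of 17.5 and mouse 3 by a factor of 4.89. All 3 pairs of mice differed in chi-square tests of the reads with and without an indel, with Benjamini-Hochberg adjusted p values of 2.10e-239 for mice 1 and 2, 2.15e-107 for mice 1 and 3, and 1.32e-23 for mice 2 and 3. Reads from PCR are not independent molecules, so these p values, the intervals and the detection limits given here cover counting error only. Gaps that all lay more than 5 bases from the cut were found at 0.0590% in mouse 1, 0.0452% in mouse 2 and 0.0518% in mouse 3, with a mean of 0.0520% ± 0.00691 (SD, n = 3). The indel share of mouse 2 lay within the counting interval of these gaps (0.0357% to 0.0564%), whereas those of mice 1 and 3 lay above theirs. Most of these gaps reached the edge of the window, and without them the share in mouse 2 was 0.0122% (0.00753% to 0.0186%), below its indel share, with a mean of 0.0161% ± 0.00444 (SD, n = 3). The indel share of mouse 2 still includes alleles with a gap at the window edge, which held 7 of its 46 deletion reads.

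**Figure D1:**
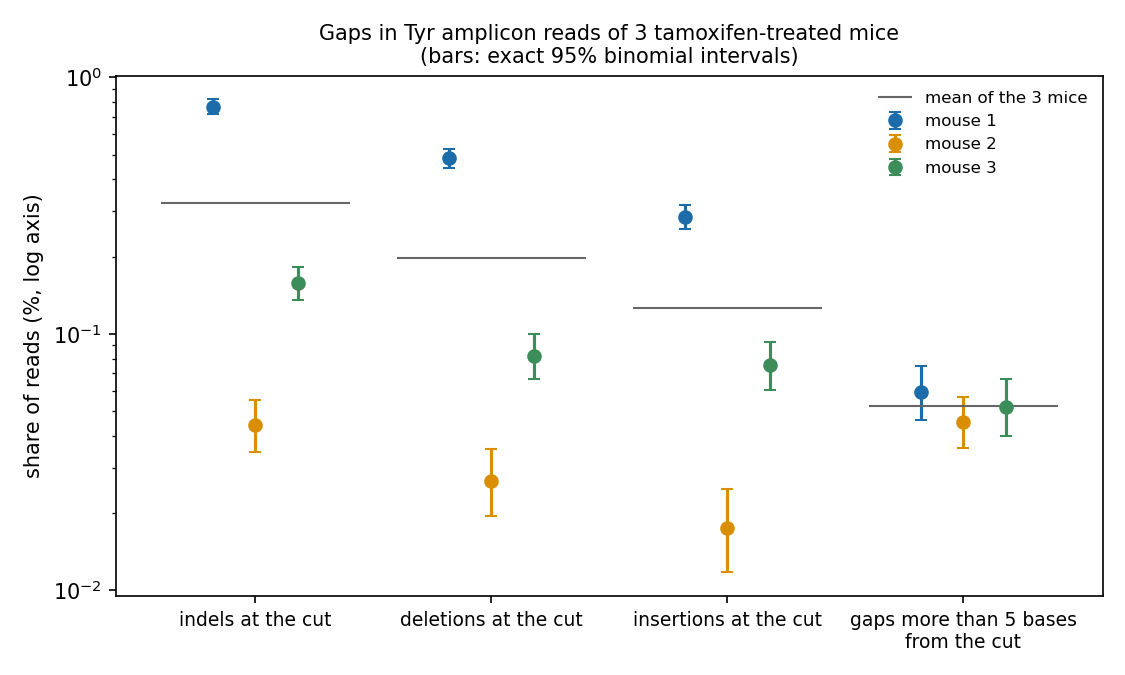
Share of reads (percent, log axis) with an indel, a deletion or an insertion at the expected cut and with gaps more than 5 bases from it, for each mouse (points, with exact 95% binomial intervals) and as the mean of the 3 mice (grey lines). Indels at the cut ranged from 0.0440% in mouse 2 to 0.769% in mouse 1, while gaps away from the cut stayed between 0.0452% and 0.0590%.

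Deletions outnumbered insertions in each mouse, with intervals that did not overlap in mouse 1 alone. Deletions were found in 0.484% of reads of mouse 1, 0.0266% of mouse 2 and 0.0819% of mouse 3, against insertions in 0.286%, 0.0174% and 0.0752%. No read had both at the cut by the deposited base numbers, which allows a share of up to 0.00253% in mouse 1, 0.00174% in mouse 2 and 0.00251% in mouse 3. Those numbers leave out gaps away from the cut. A few inserted-A reads of mouse 1 also had a deletion at the window edge, and 1 deletion read of mouse 2 had an inserted base elsewhere. The difference averaged 0.0713 percentage points ± 0.110 (SD, n = 3) and was positive in 3 of 3 mice (exact two-sided sign-flip permutation p = 0.25, adjusted p = 0.375 over 6 tests). With 3 mice, 0.25 is the smallest p this test can give, so no sign-flip comparison reported here could pass 0.05. Without mouse 1 the difference was 0.00798 percentage points, with alleles of at least 10 reads it was 0.0461, and with those of at least 0.2% of reads it turned to -0.0781. At the minimum of 10 reads, mouse 1 alone kept the mean positive. Mouse 2 then kept only the inserted A (12 reads). Mouse 3 kept an inserted A and C (71 and 13 reads) against deletions of 15 and 15 reads, so insertions led in both.

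A single inserted A at the cut was the leading indel allele in every mouse and the only allele with at least 10 reads in all of them. It was carried by 278 reads in mouse 1 (0.234% of reads, interval 0.208% to 0.263%), 12 reads in mouse 2 (0.00695%, 0.00359% to 0.0121%) and 71 reads in mouse 3 (0.0594%, 0.0464% to 0.0749%). It made up 30.4%, 15.8% and 37.8% of the indel reads of mice 1, 2 and 3, a mean of 28.0% ± 11.2 (SD, n = 3). An inserted C at the same place was found in 26, 8 and 13 reads of mice 1, 2 and 3, or 6.76% ± 3.84 of indel reads (SD, n = 3). Of these inserted-C reads, 26, 4 and 5 also carried A29C, and C18A stood in 38, 1 and 10 of the inserted-A reads of mice 1, 2 and 3 (window positions). Insertions of exactly 1 base formed 93.9% ± 5.34 of insertion reads (SD, n = 3), although counting each distinct allele a single time gave 77.4%.

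The inserted base was most often the base that precedes the cut on the guide strand, guide base 17, which is an A. It accounted for 90.7% of the 1-base insertions at the cut in mouse 1, 44.4% in mouse 2 (interval 25.5% to 64.7%, from 27 reads) and 78.9% in mouse 3. The mean of 71.3% ± 24.0 (SD, n = 3) exceeded the 25% of equal base use in 3 of 3 mice (exact two-sided sign-flip permutation p = 0.25, adjusted p = 0.375). That 25% holds only if every insertion was made at the cut itself. An A inserted elsewhere beside the A's before the cut gives the same sequence, as does a C inserted after position 21. Equal base use around the cut would thus put A above 25%. In mouse 2, whose interval starts at 25.5%, exceeding 25% therefore says little about a copied base. Counting each distinct allele a single time gave 38.9%, from 4 of 6 alleles in mouse 1 and 1 of 4 in mice 2 and 3, where each base then counts equally by construction. Inserted C followed at 8.36%, 29.6% (8 of 27 reads) and 14.4% in mice 1, 2 and 3, a mean of 17.5% ± 11.0 (SD, n = 3) that mouse 2 raises. Inserted T was at 7.78% ± 12.5 and inserted G at 3.41% ± 2.31 (SD, n = 3). Inserted T came from 6 reads in mouse 2 and 1 read in mouse 3, and it was at 0 of 311 reads in mouse 1, which allows up to 0.965% there.

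The most frequent deletions of mouse 1 were scarce or undetected in the other animals. A deletion of 6 bases (TCAACT, positions 17 to 22) was carried by 154 reads of mouse 1, or 0.130% of reads and 16.9% of its indel reads. It was found in 0 of 172680 reads of mouse 2 and 0 of 119605 reads of mouse 3, which allows shares of up to 0.00174% and 0.00251%. A deletion of 3 bases (AAC, positions 19 to 21) was found in 129 reads of mouse 1 (0.109%), in 6 reads of mouse 3 (0.00502%) and in 0 reads of mouse 2. A deletion of 20 bases, GGTTTCAACTGCGGAAACTG at positions 13 to 32, was found in 63 reads of mouse 1 and 1 read of mouse 3. The longest insertion with more than 10 reads, of 44 bases, was carried by 22 reads of mouse 1 (0.0185%) and by 0 reads of the others.

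Other deletions were found in all 3 animals. The deletion of both bases beside the cut (positions 20 to 21) was carried by 38, 8 and 15 reads of mice 1, 2 and 3, or 7.56% ± 3.20 of indel reads (SD, n = 3). A deletion of 11 bases, GGTTTCAACTG at positions 13 to 23, was carried by 47, 2 and 15 reads, or 5.25% ± 2.68 of indel reads (SD, n = 3). Of the 66 indel alleles, 6 were seen in all 3 mice, 10 in 2 mice and 50 in 1 mouse. Of the single-mouse alleles, 7 in mouse 1 and 0 in mice 2 and 3 had at least 10 reads, and many rested on 1 read. Some were the inserted A or the 6-base deletion with a second gap at the window edge. The sequencing adapter matched 2, 3 and 2 indel reads of mice 1, 2 and 3, so these counts do not measure distinct repair products alone. The 6 shared alleles held 44.0%, 47.4% and 64.9% of the indel reads of mice 1, 2 and 3, and the alleles seen in a single mouse held 33.3%, 28.9% and 20.7%.

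**Figure D2:**
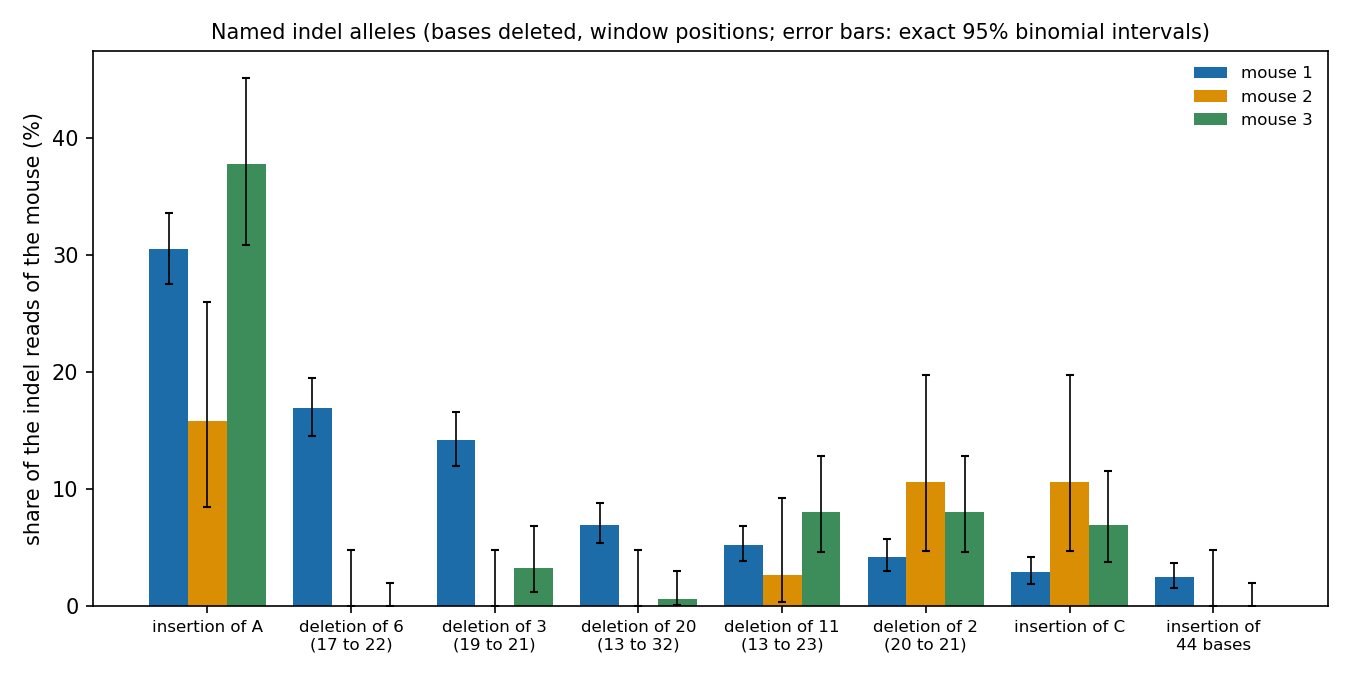
Share of each mouse's indel reads (percent) held by the 8 named indel alleles, with bars for mice 1, 2 and 3 and exact 95% binomial intervals as error bars. The inserted A led in every mouse at 15.8% to 37.8%, while the deletion of 6 bases stood at 16.9% in mouse 1 and 0 in the others.

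Allele proportions differed between the libraries beyond counting error. The effective number of indel alleles, the exponential of the Shannon entropy after thinning to 76 indel reads, was 8.89 in mouse 1, 16.6 in mouse 2 and 10.8 in mouse 3, a mean of 12.1 ± 4.04 (SD, n = 3). Restricting the count to alleles with at least 10 reads gave 3.94, and treating sequences that differ by a substitution as separate alleles gave 18.5. Permutation tests of allele proportions gave p = 1e-05 for each of the 3 pairs, the smallest these permutations can give. Chi-square tests over alleles with an expected count of at least 5 gave adjusted p values of 0.00379 for mice 1 and 2, 3.77e-16 for mice 1 and 3, and 0.0174 for mice 2 and 3. These tests, too, treat reads as independent and cover counting error only, so they do not measure differences that amplification itself adds. The libraries were counted as separate samples because the labels give separate mice.

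After thinning to equal reads, 26.7% of the 15 alleles with at least 10 reads in mouse 1 reached 10 reads in mouse 3, and all 4 such alleles of mouse 3 did so in mouse 1. Mouse 2 reached 10 reads for the inserted A alone, and in only 16 of 100 thinned draws, so its sharing was not measurable at that minimum. With a minimum of 2 reads, the share was 35.0% from mouse 1 to mouse 3 and 35.0% from mouse 3 to mouse 1. At that minimum it was 43.3% from mouse 2 to mouse 1 and 56.4% from mouse 2 to mouse 3, and 24.6% and 31.9% in the reverse directions. Over the 11 alleles present in both mouse 1 and mouse 3, the log10 read shares had a Pearson r of 0.569 (permutation p = 0.0642, adjusted p = 0.0963 over 3 pairs) and a Spearman rho of 0.551 (permutation p = 0.0821, adjusted p = 0.177). Without the alleles farthest from the median in mouse 1, a pair of them, r was 0.611. The Pearson r was 0.730 over 7 alleles for mice 1 and 2 (exact permutation p = 0.0540, adjusted p = 0.0963), where it fell to 0.109 without the farthest pair, and 0.460 over 10 alleles for mice 2 and 3 (permutation p = 0.174). The Spearman rho of these pairs was 0.655 (exact permutation p = 0.138) and 0.462 (permutation p = 0.177), with an adjusted p of 0.177 for both. These are correlations across alleles, which are not independent replicates.

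Deletion lengths differed between mice along with the leading alleles. The median deletion was 6 bases in mouse 1 (quartiles 3 and 12), 10 bases in mouse 2 (2 and 15) and 11 bases in mouse 3 (3 and 20), a mean of 9.0 ± 2.65 (SD, n = 3). Reads pooled over the mice had a median of 6 bases, the value of mouse 1, which supplied most deletion reads. Deletions of 3 to 9 bases made up 56.3% of the deletion reads of mouse 1, against 6.52% in mouse 2 and 19.4% in mouse 3. Deletions of 10 or more bases made up 34.7%, 60.9% and 58.2%. Deletions whose gap at the cut reached the edge of the window held 10.3%, 10.9% and 11.2% of deletion reads (59, 5 and 11 reads), and the longest deleted length recorded was 85, 48 and 84 bases in mice 1, 2 and 3. These rested on 1, 4 and 5 reads. Among deletions with at least 10 reads the longest was 84 bases in mouse 1 and 11 bases in mouse 3, and mouse 2 had none.

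The net length of the indel was not a multiple of 3 in 57.9% of the indel reads of mouse 1, 76.3% of mouse 2 and 85.1% of mouse 3. The mean frameshift share, 73.1% ± 13.9 (SD, n = 3), differed from the 66.7% of equal frame use by less than the spread between mice (2 mice above and 1 below; exact two-sided sign-flip permutation p = 0.5, adjusted p = 0.5). Pooling the reads gave 63.5%, below that reference, since mouse 1 then dominates. In mouse 1 the deletions of 6 and 3 bases were the leading in-frame alleles, and 42.1% of its indel reads were in frame. Frameshift reads amounted to 0.446%, 0.0336% and 0.134% of all reads in mice 1, 2 and 3. The frame was taken from the deposited length of the gap at the cut, and was not set against an exon annotation. An allele of 13 reads in mouse 1 has a second gap, and counting all gaps of such alleles gave 56.5% in mouse 1 and a mean of 72.6%.

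Many deletions were flanked by short repeats. The deletions of 11 and 20 bases were each flanked by 2 identical bases, those of 6 and 3 bases by 1, and that of positions 20 to 21 by 0. At least 2 identical bases flanked 24.7% of the single deletions inside the window in mouse 1 (123 of 498 reads), 31.6% in mouse 2 (12 of 38) and 38.6% in mouse 3 (32 of 83). Equal use of all placements of the same lengths would give 5.53%, 13.2% and 13.0%. The excess was 21.0 percentage points ± 3.92 (SD, n = 3), positive in 3 of 3 mice (exact two-sided sign-flip permutation p = 0.25, adjusted p = 0.375). Requiring at least 3 identical bases left an excess of 0.304, 5.04 and 9.15 percentage points in mice 1, 2 and 3, a mean of 4.83.

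Deletions showed no common direction from the cut. The bases removed on the PAM-distal side minus those on the PAM-proximal side averaged -1.04 per deletion read in mouse 1, 1.24 in mouse 2 and 1.54 in mouse 3, a mean of 0.580 ± 1.41 (SD, n = 3; exact two-sided sign-flip permutation p = 0.5, adjusted p = 0.5). The sign turned with the weighting, to -0.551 with pooled reads and -0.553 with each distinct allele counted a single time, and the mean was 1.39 without mouse 1, 0.252 without mouse 2 and 0.0993 without mouse 3. Leaving out the alleles with a gap at the window edge gave 1.38. Only bases inside the window were counted, so deletions that cross its edge entered in part. Deletions of 84 bases in 17 reads of mouse 1 and 5 reads of mouse 3 are examples. Deletions flanked by identical bases kept the deposited placement among equivalent ones. The size of the difference in each mouse therefore depends on the window and on the alignment.

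Substitutions in reads without gaps were dominated by A19C (window position 19, guide base 16), which was carried by 5.33% of such reads in mouse 1, 5.20% in mouse 2 and 5.45% in mouse 3, a mean of 5.33% ± 0.121 (SD, n = 3). The next most frequent change, T15C, stood at 0.366% ± 0.0295 (SD, n = 3). The rate within 3 bases of the cut was 1.14% per base ± 0.0256, against 0.210% ± 0.00188 more than 5 bases away (SD, n = 3). Their difference was 0.930 percentage points ± 0.0258 (SD, n = 3), positive in 3 of 3 mice (exact two-sided sign-flip permutation p = 0.25, adjusted p = 0.375). It rested on that single position, since leaving out position 19 brought the difference to 0.0243 percentage points. A near region of 1 base on either side, which leaves that position out, gave 0.104, and one of 5 bases gave 0.558. The highest over the lowest mouse was 1.05 for A19C and 17.5 for the indel share.

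**Figure D3:**
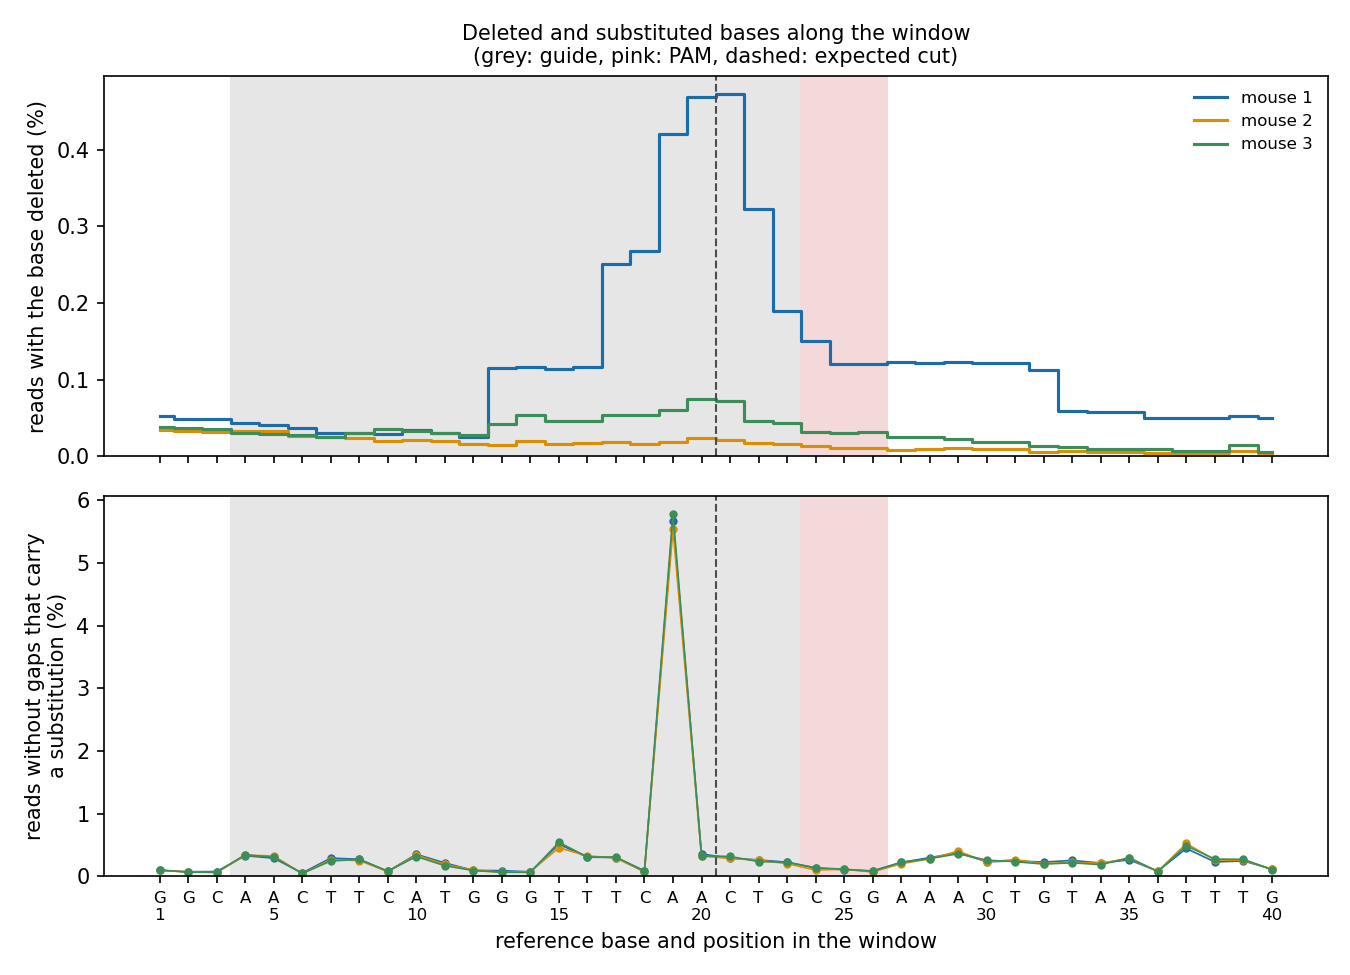
Percent of reads with each window base deleted (top) and percent of reads without gaps with a substitution at each base (bottom), for mice 1, 2 and 3, along the 40 bases of the window, with the guide in grey, the PAM in pink and the expected cut as a dashed line. Deleted bases peaked beside the cut in mice 1 and 3 (0.473% at position 21 and 0.0744% at position 20). In mouse 2 they were highest at the 5′ window edge (0.0347% at position 1, against 0.0243% at position 20). The substitution profile of the 3 mice was nearly superimposed and peaked at position 19, where A19C stood at 5.20% to 5.45%.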

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

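The alternatives without adapter matches, without position 19, with distinct deletion products, with a permutation test over all alleles, without gaps at the window edge for gaps away from the cut, with all gaps of an allele for the frame, and those leaving out a mouse for allele sharing and for the pairs of mice, were chosen after seeing the data. Of 94 alternative values, 78 kept their direction or stayed within 1 SD of the mice, 12 moved further and 4 turned direction. With 3 mice no sign-flip test could pass 0.05, so direction alone was followed there. Leaving out 1 mouse cannot move a mean of 3 mice by 1 SD, nor turn a direction that all 3 share. Such values among the 78 were fixed in advance and say nothing about stability. The SD of the indel share exceeds its mean, so staying within it says little: it ranged from 0.0781% to 0.947%. Counting each distinct allele a single time gave a templated base share of 38.9%, but it weights each inserted base nearly equally and is no test of that share. In the other alternatives run, the templated base share (61.7% to 92.0%), the homology excess (4.83 to 26.3 percentage points) and the near minus far substitution rate (0.0243 to 0.944 percentage points) stayed on 1 side. The 92.0% came from alleles with at least 10 reads, which left the inserted A alone in mouse 2 and dropped inserted G and T in mouse 3. The share of mouse 2 was thus fixed by that minimum, which is no test of it. Among alleles with at least 0.2% of reads, the indel share became 0.0781%, deletions minus insertions -0.0781 percentage points and gaps away from the cut 0.0%, because only the inserted A of mouse 1 passed among indels and no gap away from the cut did. Pooling reads, which weights mouse 1 most, gave a frameshift share of 63.5%, a median deletion of 6 bases and a PAM-distal minus PAM-proximal difference of -0.551 bases. Counting each distinct allele a single time gave -0.553 bases for that difference and 77.4% for 1-base insertions. Alleles with at least 10 reads gave 3.94 effective alleles and 0.00193% gaps away from the cut. Keeping substitutions apart gave 18.5 effective alleles; the cause is the splitting of alleles. Counting every allele not marked unedited as edited gave 0.947%, which adds substitutions beside the cut, and gaps more than 10 bases away came to 0.0289%. Leaving out gaps that reach the window edge gave 0.0161% for gaps away from the cut. Leaving out a mouse leaves 1 pair of mice, and this 1 pair differed each time. The minimum of 0.2% did not leave a value in all 3 mice for frameshift, 1-base insertion, templated base, homology, deletion length, direction, effective number and allele proportions, nor did the minimum of 10 reads for homology, deletion length and direction. Keeping deletions at the window edge in the homology measure was not run, because their outer end is not shown. The number of indel reads, 76, limits mouse 2 most, although its library is the deepest.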

Other observations

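The test of short gaps by junction and that of a second change in A19C reads were chosen before their results were seen; all others in this part were chosen after. The 44-base insertion of mouse 1 shows its first 20 bases, ACTGTAAGTTTGAAACTTAC, in the window. Its first 12 bases, ACTGTAAGTTTG, equal window positions 29 to 40, and the next 8, AAACTTAC, equal the opposite strand of positions 32 to 39. Outside the named alleles, and chosen after their values were seen, the alleles found in all 3 mice included a deletion of 12 bases at positions 15 to 26 (10, 5 and 3 reads in mice 1, 2 and 3), flanked by 2 identical bases, and an inserted G (3, 1 and 5 reads). A deletion of 24 bases at positions 8 to 31, flanked by 4 identical bases, was found in mice 2 and 3 (4 and 7 reads) and in 0 reads of mouse 1. A deletion of 84 bases from position 18 on was found in 17 reads of mouse 1, and a different deletion of 84 bases, ending at position 21, in 5 reads of mouse 3.

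The inserted C travelled with other changes. A29C was present in 26 of 26 inserted-C reads of mouse 1, 4 of 8 of mouse 2 and 5 of 13 of mouse 3, and 23, 3 and 5 of these reads carried G36T as well. In reads without gaps, A29C and G36T stood together in 37, 43 and 26 reads of mice 1, 2 and 3, that is 0.0314%, 0.0249% and 0.0218%. G36T stood in 73, 94 and 60 reads without gaps in all, so it was linked to A29C there too. Whether the inserted-C reads with these changes are repair products was not tested, and they are counted among the 1-base insertions above. In mouse 1, 11 of the 21 reads with a deletion of positions 19 to 24 carried A27C.

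The indel share differed between mice by a factor of up to 17.5. Spill-over of reads from mouse 1 is argued against as the source of the indels of mouse 3, since their allele proportions differed (permutation p = 1e-05, the smallest possible) and the 6-base deletion, expected in 31.7 reads of mouse 3 by that route, was found in 0. With 3 counts as the limit, which lies below the exact bound, the same allele limits spill-over to 1.95% of the reads of mouse 1, or 17.8 indel reads. Mouse 3 had 188 indel reads and mouse 2 had 76. In mouse 2 the 6-base deletion was expected in 12.8 reads if all indels came from mouse 1, and was found in 0. Spill-over of a part of the indel reads of mouse 2 is not excluded by this limit. Adapter sequence aligned as an indel matched 3.95% of the indel reads of mouse 2. Alleles that show fewer than 20 bases in the window, such as long deletions, could not be called a match, so this is a lower limit. For mouse 2, whose indel share is near that of gaps elsewhere only if gaps at the window edge are counted (0.0452% with them, 0.0122% without), error spread evenly over the window is argued against, as short gaps at the cut were 64.3 times as frequent as the mean of the 38 other junctions (exact interval 38.7 to 109). The other junctions were uneven: 27 of them had 0 reads with a short gap, and the highest, after position 14, had 10 against 44 at the cut, a ratio of 4.4 (exact interval 2.18 to 9.81). Both ratios were raised by the way gaps were assigned to junctions. Short deletions that touch the cut were all counted at it, and the junctions after positions 19 and 21 stood at 0 reads in mouse 2. Inserted A and C were also placed at the cut among equivalent placements, and 1-base insertions made up 27 of the 44 reads. Error particular to the cut junction is not excluded by this comparison. Differences in Cre activation, tamoxifen intake or the growth of edited cells between animals remain open and untested, as does the number of cells sampled.

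A19C, at about 5% of reads in each mouse, did not follow the indel share: the highest over the lowest mouse was 1.05, which argues against editing at the cut. The same change in the other CAAC of the window, A4C, reached at most 0.0307 of the A19C share, and no other substitution was present in more than 0.622% of A19C reads, against a template that differs at several bases of the window. An inserted A combined with A19C can be aligned as an inserted C elsewhere, so it was counted by sequence, whatever the alignment. It was found in 0 reads beside 361 inserted-A reads, where 19.3 were expected (upper 95% bound 1.02%). With positions counted from the 3′ side, the same change was found in 5 reads, all of mouse 1 (1.37% of 366 reads, exact interval 0.445% to 3.16%). The loss is what an error that depends on a longer stretch of sequence needs, and 49 of the 361 reads carried C18A, but it does not single that error out. An error tied to the read cycle alone would keep its share in either the 5′ or the 3′ count. Both upper bounds, 1.02% and 3.16%, lie below the lowest 95% bound of A19C in reads without gaps, 5.10%. This argues against a cycle error alone over the pooled inserted-A reads, which come mostly from mouse 1, within counting error. A template that differs at this base alone may be cut less often and would lack A19C in edited reads too, so it remains open.

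C18A was carried by 38 of 278 inserted-A reads of mouse 1 (13.7%, exact interval 9.86% to 18.3%), 1 of 12 of mouse 2 and 10 of 71 of mouse 3 (14.1%), against 0.0595%, 0.0417% and 0.0377% of the reads without gaps. Independent background error is argued against by this excess. A single edited cell lineage with both changes, present in 1 animal, is argued against by its presence in all 3 mice, and no difference between mice 1 and 3 was detected (Fisher exact p = 1.0). C18A is not the only change tied to an indel allele. In mouse 1 the most frequent substitution was C6A in 12 of 154 reads of the 6-base deletion, G40T in 12 of 129 of the 3-base deletion and T7G in 6 of 63 of the 20-base deletion, each picked as the highest of its allele. An error that recurs during PCR or sequencing, on this or other sequences, is a candidate explanation, and separate lineages in each mouse remain open.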
